A study of Homo sapiens with 6 samples.

How the data were processed

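RNA was measured in NALM6 cells, grown in RPMI with 10% FBS, after 48 h with verteporfin or with DMSO, in 3 libraries per group. Per the labels, total RNA was taken up in Trizol and sequenced after a KAPA stranded library preparation. The verteporfin concentration, 0.6 mmol/L, is printed as the labels give it. The replicates carry numbers, but nothing in the labels says that equal numbers share a day or a culture, so treatment was the 1 term of the model and the replicate number served only as an alternative.

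The deposited values are FPKM (fragments scaled to transcript length and library size), computed by the authors for each Ensembl transcript. The submitters' processing notes name FastQC, cutadapt, HISAT2 2.1.0, StringTie 1.3.3, STAR and edgeR and the build hg18, without the role or order of each. Most transcripts (61862) carry identifiers of a GENCODE release mapped back to GRCh37, so the build behind the values is uncertain and no coordinates are given. Each transcript listed has a mean of at least 0.5 FPKM in 1 group or both, so transcripts below that in both groups are missing from the sums. A further set of entries holds whole numbers (tolerance 0) under 2939 repeated transcript identifiers. These are not FPKM, were left out of each gene and list test and are described in the closing section. Read depth is unknown, because no read counts are given, so no counting interval could be computed and the spread between libraries sets the precision.

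Gene names came from GENCODE 29. It matched 61975 transcripts by identifier; 275 (0.442%) were unmatched and left out. FPKM of the transcripts of a gene were summed to 13494 genes, of which 10982 are protein coding. Sums of per-transcript FPKM depend on how reads were shared between transcripts, and between paralogs. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2 of FPKM + 1 with limma 3.58.1 (eBayes with a variance trend, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 12952 genes and a threshold of 0.05. A log2 fold change is verteporfin minus DMSO, with a 95% interval and standard error from limma. A count of genes changed at least 2-fold used an absolute log2 fold change of 1 beside the threshold. Measures of whole libraries were compared with 2-sided exact permutation tests, adjusted over the 9 measures. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

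There were 22 gene lists, written from textbook knowledge: Hippo core, YAP-TEAD targets, p53 targets, ATF4 amino acid response, ER chaperones, NRF2 targets, heat shock, autophagy and lysosome, cholesterol synthesis, glycolysis and hypoxia, the nuclear and the mitochondrial respiratory chain, G1/S and replication, G2/M, MYC and ribosome biogenesis, B-cell precursor, B-cell maturation, other cell types, interferon response, NF-kB and immediate early, BCL2 family, and heme and porphyrin. Each was tested against other genes with camera from limma at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Genes of a list were also counted adjusted over the list alone.

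The rule for named genes took the 8 genes with the largest change in each direction among those past the threshold with a mean of at least 1 FPKM and groups that do not overlap, up to 3 passing genes of each list, and 19 fixed genes of the Hippo pathway and heme breakdown, of which 8 were tested. Genes that were higher or lower adjusted over a list alone, genes with an adjusted p under 0.1 and all others named were chosen after their values were seen. The tests, lists, rule for names and the first group of alternative settings below were set before the data were examined.

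The first group of alternative settings were no minimum, a minimum mean of 5 FPKM, pseudocounts of 0.1 and 0.01, equal medians, quantile normalization, limma without a trend, the replicate number as a block, and leaving out each library in turn. Settings meant for read counts were not run, because the values are FPKM. After the data were seen, the libraries numbered 2 were left out together, values were rescaled without the 3 most abundant transcripts, library weights were estimated, and single transcripts were tested in place of genes. The gene test was tried on simulated data of 12952 genes in 20 runs. It called 6.5%, 65.2%, 86.5% and 94.6% of genes changed by 1, 2, 3 and 4 on the log2 scale and 0.0423% of unchanged genes. Changed genes were drawn only from those with a mean log2 of FPKM + 1 of at least 3, so genes of lower FPKM were not covered. Camera called 40 of 40 simulated lists of 25 genes shifted by 0.5 and 1 of 400 unshifted lists. Simulated genes varied independently of each other, while genes of the called lists had estimated correlations of up to 0.424. These rates thus do not give the rate of false calls in the data.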

Results

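RNA was sequenced from NALM6 cells, an established human line of B-cell precursor acute lymphoblastic leukemia. The cells had been kept for 48 h with verteporfin or with DMSO, the solvent. Verteporfin is a porphyrin known as an inhibitor of the binding of the coactivator YAP to TEAD transcription factors, the last step of the Hippo pathway, and the study asked how expression of Hippo pathway genes compares without and with the drug. The labels give its concentration as 0.6 mmol/L, which is high for a drug in culture, so that the unit may not be the one meant. There were 3 libraries per group. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Values were FPKM per transcript, summed here to 13494 genes, of which 12952 passed the minimum of a mean of 0.5 FPKM and were tested. Read depth is unknown, because FPKM do not keep it. The share of transcripts listed at 0 was 15.7% ± 2.58 in DMSO and 8.16% ± 3.07 in verteporfin (SD, n = 3), and every verteporfin library had a lower share than every DMSO library. The 2-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 allow, and 0.18 adjusted over the 9 measures of the libraries compared.

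**Figure D1:**
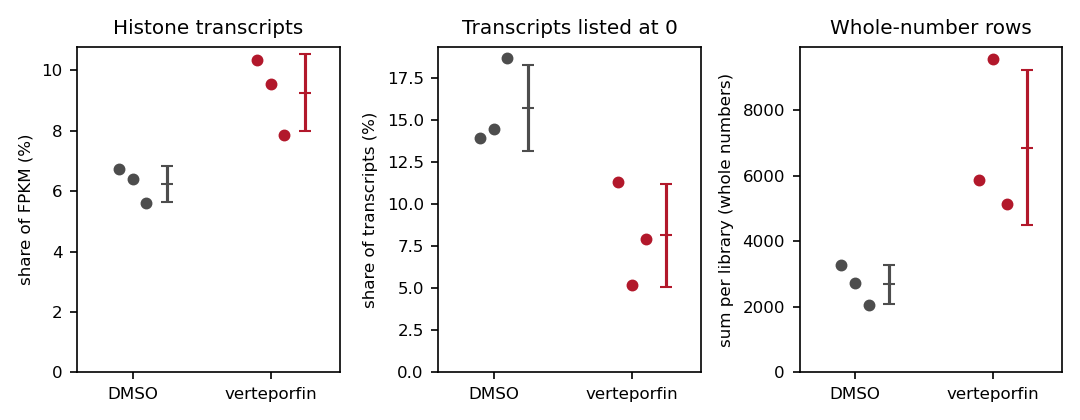
Measures of each library, DMSO in gray and verteporfin in red: the percent of summed FPKM in histone genes, the percent of transcripts listed at 0, and the sum of a separate set of whole numbers that are not FPKM. Points are libraries and the bars are the mean and SD (n = 3); the percent at 0 lies between 14.0 and 18.7 with DMSO and between 5.23 and 11.3 with verteporfin.

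Verteporfin raised 2 genes, both known as targets of the stress-induced transcription factor ATF4. DDIT4 (ENSG00000168209), which encodes an inhibitor of mTORC1, rose from 45.6 ± 9.15 to 261 ± 69.4 FPKM (SD, n = 3), a log2 fold change of 2.48 with a standard error of 0.30 and an adjusted p of 0.0441 by limma. DDIT3 (ENSG00000175197), which encodes the transcription factor CHOP, rose from 6.77 ± 0.600 to 42.2 ± 9.63 FPKM (SD, n = 3), a log2 fold change of 2.45 with a standard error of 0.30 and the same adjusted p. Both were higher in each of the 3 verteporfin libraries than in any DMSO library, both changed at least 2-fold, and 0 genes fell in this test, unlike with a replicate block or library weights (40 and 388 lower). At an unadjusted p under 0.05 limma gave 1145 genes, 565 higher and 580 lower, where chance gives 648. Among other splits of the libraries, 3 against 3, those with 2666 and 1164 such genes exceeded this count, and the rest gave 143 to 651. An excess this large thus also arose in some splits that the treatment does not follow. The groups did not overlap for 1842 genes, or 14.2% of those tested, against 10% by chance.

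A further 13 genes lay between an adjusted p of 0.05 and 0.1, all with higher values in verteporfin. They did not pass the test and were singled out after their values were seen. With the replicate number as a block all of those named in this paragraph passed, with adjusted p values from 0.0113 (CD69 and ASS1) to 0.0231 (JUN). Among them were PPP1R15A, which encodes a phosphatase subunit that reverses the block of translation in stressed cells (log2 fold change 3.07, adjusted p = 0.0811), and the inducible chaperone gene HSPA6 (3.51, adjusted p = 0.0811). The lymphocyte activation marker CD69 had a log2 fold change of 2.65 and the urea cycle enzyme gene ASS1 one of 1.98, each with an adjusted p of 0.0811. INHBE, a gene of the activin family, had a log2 fold change of 2.71 (adjusted p = 0.0892), and JUN, a subunit of AP-1, one of 4.50 (adjusted p = 0.0968). CYTL1 (2.44), DUSP16 (2.38), the histone gene H2AC6 (2.74) and PDCD4 (1.81) had the same direction. In JUN the verteporfin libraries were far apart, at 33.6, 53.7 and 299 FPKM, against 1.38 to 7.41 FPKM in DMSO.

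Among simulated genes changed by 2 on the log2 scale limma called 65.2%, and among those changed by 1 it called 6.5%. Changes in genes of low FPKM were not simulated. The count of 2 depended on the model, the libraries and the scale of the values. With the replicate number as a block limma called 84 genes, 44 higher and 40 lower, and with library weights, tried after the data were seen, 1081 genes, 693 higher and 388 lower, both genes included each time. Of 87 genes named in the text, 23 that did not pass in the test without these terms did so with the block, and 57 with the weights. Verteporfin replicate 3 had a weight of 3.88, against 0.416 and 0.363 for verteporfin replicates 1 and 2. Without DMSO replicate 1, DMSO replicate 2 or verteporfin replicate 3 limma called 0 genes, with 726, 1304 and 854 genes at an unadjusted p under 0.05; without DMSO replicate 3 it called 1 other gene, without verteporfin replicate 1 it called 11 and without verteporfin replicate 2 it called 12, both genes included. With a pseudocount of 0.1 or 0.01, equal medians or no trend in the variance limma also called 0 genes, with 1083 to 1172 at an unadjusted p under 0.05, while DDIT3 and DDIT4 kept log2 fold changes of 2.41 to 2.62.

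**Figure D2:**
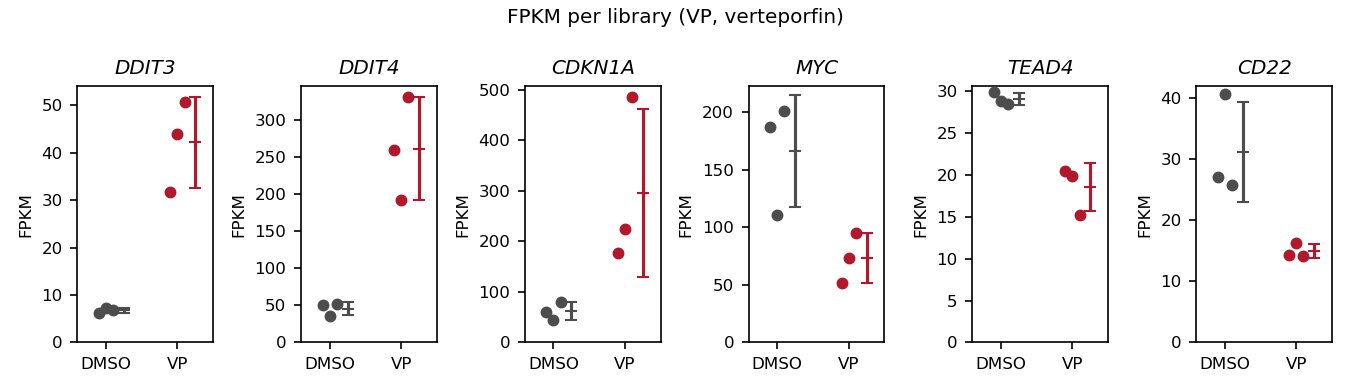
FPKM of 6 genes in each library, DMSO in gray and verteporfin (VP) in red, each axis from 0. Points are libraries and the bars beside them are the mean and SD (n = 3). DDIT3 and DDIT4 passed the test over all genes, and CDKN1A, MYC, TEAD4 and CD22 did not; DDIT3 lay between 31.8 and 50.8 FPKM with verteporfin and between 6.10 and 7.27 FPKM with DMSO.

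Genes of the Hippo pathway itself, the question of the study, did not move together. Of the 40 genes of the Hippo core list 29 were tested. None rose or fell, over all genes or adjusted over the list alone; 15 had a log2 fold change above 0 and 14 one below 0. TEAD4, the 1 TEAD transcription factor tested, was at 29.1 ± 0.721 FPKM in DMSO and 18.5 ± 2.87 FPKM in verteporfin (SD, n = 3), lower in each of the 3 verteporfin libraries. Its log2 fold change was -0.63 (95% interval -1.23 to -0.04), with an unadjusted p of 0.0396 and an adjusted p of 0.539 by limma. Single TEAD4 transcripts ranged from -1.25 (ENST00000540314) to 0.16 (ENST00000397122). The most abundant, ENST00000358409, had a log2 fold change of -0.15 (adjusted p = 0.971 by limma on single transcripts). NF2, which encodes the upstream activator merlin, was at 25.6 ± 4.56 FPKM in DMSO and 17.5 ± 1.90 FPKM in verteporfin (log2 fold change -0.51, adjusted p = 0.612).

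Among the kinases of the pathway differences of either sign had wide intervals that included 0. STK4 and STK3, the mammalian Hippo kinases, had log2 fold changes of 0.24 (95% interval -0.62 to 1.09) and 0.22 (-0.49 to 0.93). LATS1, which phosphorylates YAP, was at 4.67 ± 2.61 FPKM in DMSO and 6.96 ± 2.91 FPKM in verteporfin (log2 fold change 0.56, 95% interval -0.49 to 1.60, and 0.08 without DMSO replicate 1). TAOK2, a kinase upstream of STK3 and STK4, was at 35.5 ± 2.62 FPKM in DMSO and 25.9 ± 5.05 FPKM in verteporfin, with lower values in each verteporfin library (log2 fold change -0.46, adjusted p = 0.649). The scaffold gene SAV1 had a log2 fold change of 0.10, the kinase cofactor gene MOB1A one of -0.19 and VGLL4, a TEAD cofactor that competes with YAP, one of 0.23. These small values moved when single libraries were left out, and those of STK4, SAV1 and MOB1A turned sign. Without verteporfin replicate 2 STK4 was at -0.015 and STK3 at 0.13, and without DMSO replicate 2 SAV1 was at -0.06 and VGLL4 at 0.39. Without verteporfin replicate 1 MOB1A was at 0.04 and STK3 at 0.37. STK3 and VGLL4 stayed above 0 whichever library was left out. The largest differences in the list were those of RASSF1 (0.78, adjusted p = 0.572) and AMOT (-0.67, adjusted p = 0.599), chosen after their values were seen. RASSF1 was at 0.51 without verteporfin replicate 3 and 1.20 without verteporfin replicate 2, and AMOT at -0.39 without DMSO replicate 1. With library weights, tried after the data were seen, TEAD4 (-0.82, adjusted p = 0.03) and RASSF1 (1.19, adjusted p = 0.0207) passed over all genes. That fit rested largely on verteporfin replicate 3, with a weight of 3.88 against 0.416 and 0.363 for verteporfin replicates 1 and 2. RASSF1 was at 31.0, 13.7 and 37.1 FPKM in verteporfin replicates 1, 2 and 3, against 13.1 to 16.1 FPKM in DMSO. YAP1, WWTR1, TEAD1, TEAD2, TEAD3, LATS2 and AMOTL2 had no matched transcript among the FPKM values, which start at a mean of 0.5 FPKM in a group. They could not be tested. By camera the list did not stand apart from other genes (adjusted p = 0.906, and 0.908 with an estimated correlation). Its median was 0.04 and its mean 0.01, while camera gave the direction as down, so that it has no clear sign. Without DMSO replicate 3 (adjusted p = 0.855) or verteporfin replicate 2 (0.743), with a mean minimum of 5 FPKM (0.81) or after quantile normalization (0.787) the direction turned to up.

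Of the 22 genes of the list of YAP and TEAD targets 5 were tested, and 0 passed over all genes. FJX1, which encodes a secreted kinase-like protein, was at 48.5 ± 21.1 FPKM in DMSO and 16.0 ± 8.20 FPKM in verteporfin (SD, n = 3), a log2 fold change of -1.58. CRIM1, which encodes a membrane protein that binds bone morphogenetic proteins, was at 47.1 ± 2.34 and 28.0 ± 5.12 FPKM, a log2 fold change of -0.74. Neither passed over all genes (adjusted p = 0.418 and 0.461 by limma), while FJX1 did with the replicate block (adjusted p = 0.0252) and with library weights (0.0333). Both were lower when adjusted over the list alone (adjusted p = 0.0378 and 0.0456). ASAP1 (-0.33) and ARHGEF17 (-0.41) were below 0 and GADD45A (0.40), also a known p53 and stress target, above 0, each with an interval that included 0. Without verteporfin replicate 3 GADD45A was at 0.0099 and ASAP1 at -0.05, and without DMSO replicate 1 ARHGEF17 was at 0.03. The list was not called by camera (adjusted p = 0.0714, and 0.473 with an estimated correlation). CCN1, CCN2 and ANKRD1, the usual readouts of YAP activity, had no matched transcript among the FPKM values and could not be tested.

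**Figure D3:**
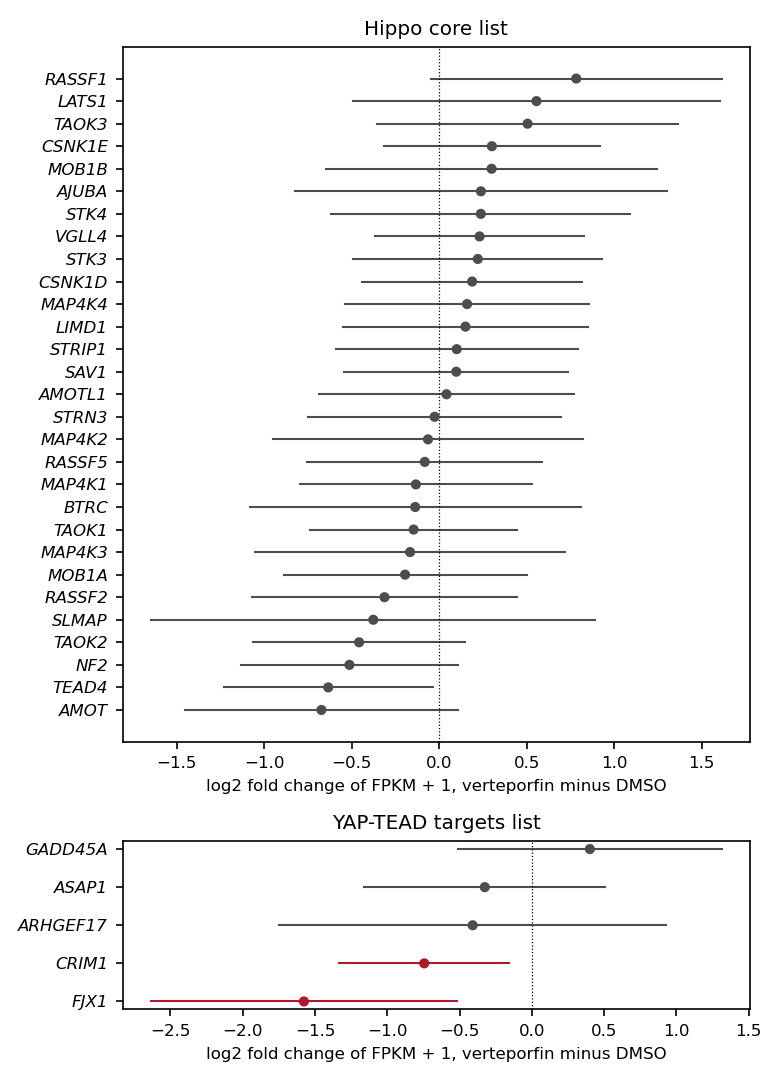
Log2 fold change, verteporfin minus DMSO, of FPKM + 1 for the 29 tested genes of the Hippo core list and the 5 of the YAP-TEAD targets list, with 95% intervals from limma (n = 3 per group). Red marks genes with an adjusted p under 0.05 over the list alone, which were FJX1 and CRIM1; the Hippo core genes lie from -0.67 (AMOT) to 0.78 (RASSF1).

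The strongest movement was in targets of ATF4, the factor that responds to amino acid shortage and to phosphorylation of the translation factor eIF2. Of the 25 tested genes of the list 23 had a log2 fold change above 0, 2 rose over all genes (DDIT3 and DDIT4) and 0 fell. Camera called the list upward (adjusted p = 4.93e-18), but not with an estimated correlation of 0.229 between its genes (adjusted p = 0.373). Adjusted over the list alone 15 genes were higher. Besides DDIT4 and DDIT3, those with the largest log2 fold changes were the stress transcription factor gene ATF3 (3.08), PPP1R15A (3.07) and CHAC1 (2.19), which encodes an enzyme that degrades glutathione. SESN2, an inhibitor of mTORC1 signaling, was at 14.0 ± 3.57 FPKM in DMSO and 65.1 ± 32.1 FPKM in verteporfin (log2 fold change 2.02), and the pseudokinase gene TRIB3 had a log2 fold change of 1.91.

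Of the same 15, ASNS, asparagine synthetase, was at 14.4 ± 3.21 and 54.9 ± 31.1 FPKM (log2 fold change 1.74), and the transfer RNA synthetase genes WARS1 (1.36), SARS1 (1.06) and AARS1 (1.00) were higher in each verteporfin library. The cystine transporter gene SLC7A11 (1.63) and its partner SLC3A2 (1.05), the hormone gene STC2 (1.12) and the transcription factor gene CEBPB (1.87) complete the 15. In SLC7A11 the groups overlapped, with 0.324 FPKM in verteporfin replicate 1, without which its log2 fold change was 2.48 and it passed over all genes (adjusted p = 0.0425). ATF4 itself was at 217 ± 26.6 FPKM in DMSO and 303 ± 95.2 FPKM in verteporfin (log2 fold change 0.44, 95% interval -0.24 to 1.12), with log2 fold changes of 0.71 without verteporfin replicate 1 and 0.23 without verteporfin replicate 2. SLC7A5, the leucine transporter gene, went the other way, with a log2 fold change of -0.60 (adjusted p = 0.545). PHGDH, the first enzyme of serine synthesis, had a log2 fold change of 0.53 (adjusted p = 0.633) and the glycyl-tRNA synthetase gene GARS1 one of 0.63 (adjusted p = 0.668), and neither passed adjusted over the list alone. GARS1 was at 0.20 without verteporfin replicate 2 and PHGDH at 0.28 without verteporfin replicate 1. The median of the list was 1.06. The verteporfin libraries differed among themselves, and ATF3 was at 10.3, 23.9 and 115 FPKM in them. The same 3 libraries had the lower share of transcripts at 0 and the higher share of FPKM in histone genes, 9.26% ± 1.26 against 6.25% ± 0.589 in DMSO (SD, n = 3).

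**Figure D4:**
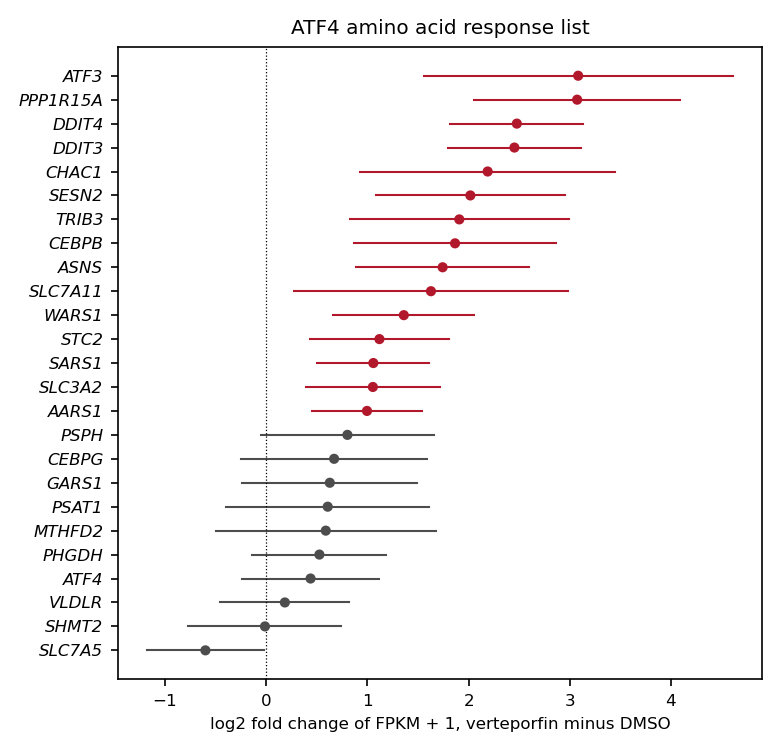
Log2 fold change, verteporfin minus DMSO, of FPKM + 1 for the 25 tested genes of the ATF4 amino acid response list, with 95% intervals from limma (n = 3 per group). Red marks the 15 genes with an adjusted p under 0.05 over the list alone, from AARS1 (1.00) to ATF3 (3.08); SLC7A5 lies at -0.60.

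Targets of p53 were called upward as a list by camera (adjusted p = 6.7e-07, median 0.46), but not with an estimated correlation (adjusted p = 0.385). Of 21 tested genes 0 passed over all genes and 6 were higher adjusted over the list alone. CDKN1A, which encodes the cell cycle inhibitor p21, was at 61.9 ± 18.1 FPKM in DMSO and 296 ± 166 FPKM in verteporfin (SD, n = 3), a log2 fold change of 2.14 (adjusted p = 0.148 over all genes by limma, and 0.0113 with the replicate block). The antiproliferative gene BTG2 had a log2 fold change of 1.73, BBC3, which encodes the death activator PUMA, one of 1.94, and the death receptor gene TNFRSF10B one of 1.28. TP53INP1 (1.31) and GDF15 (2.57) were the others. GDF15, a secreted stress marker, was listed at 0 in a pair of DMSO libraries and at 0.232 FPKM in the other, and at 1.41, 2.48 and 30.0 FPKM in verteporfin (log2 fold change 1.43 without verteporfin replicate 3). BBC3, TNFRSF10B and GDF15 are known to respond to ATF4 and CHOP as well as to p53. MDM2, a p53 target and its ubiquitin ligase, had a log2 fold change of 0.24 (95% interval -0.56 to 1.05), and -0.04 without DMSO replicate 1.

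The BCL2 family of death regulators was called upward by camera (adjusted p = 0.0496), but not with an estimated correlation (adjusted p = 0.473). Of 14 tested 0 passed over all genes and 3 were higher adjusted over the list alone: BBC3, BMF (1.85) and HRK (1.16), which all encode activators of cell death. PMAIP1, which encodes NOXA, had a log2 fold change of 1.35 (adjusted p = 0.461), and 0.80 without verteporfin replicate 3. Other activators went the other way: BID had a log2 fold change of -0.66 (adjusted p = 0.547) and BCL2L11, which encodes BIM, one of -0.64 (adjusted p = 0.572), both with lower values in each verteporfin library. The call was also lost without DMSO replicate 2 (adjusted p = 0.21), verteporfin replicate 1 (0.281) or verteporfin replicate 3 (0.113).

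MYC and genes of ribosome biogenesis were called downward as a list by camera (adjusted p = 6.7e-07, median -0.63). The call was lost with an estimated correlation of 0.424 (adjusted p = 0.473) and without verteporfin replicate 1 (adjusted p = 0.0521). Of 23 tested 22 had a log2 fold change below 0, 0 passed over all genes and 3 were lower adjusted over the list alone. MYC, the transcription factor that drives these genes, was at 166 ± 48.3 FPKM in DMSO and 73.2 ± 21.7 FPKM in verteporfin (SD, n = 3), a log2 fold change of -1.17 (adjusted p = 0.404 over all genes by limma). Most of this difference lay in 1 MYC transcript, ENST00000613283, at 50.9 to 152 FPKM in DMSO and 14.3 to 39.2 FPKM in verteporfin (adjusted p = 0.622 by limma on single transcripts). The other MYC transcripts went both ways, with log2 fold changes from -2.43 to 0.73. RRS1, a ribosome assembly factor, had a log2 fold change of -1.28 and SRM, spermidine synthase, one of -1.16. NCL, which encodes nucleolin, was at 381 ± 25.6 and 238 ± 97.0 FPKM (log2 fold change -0.77, adjusted p = 0.563, and -0.38 without verteporfin replicate 1).

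Camera also called the genes of cholesterol synthesis downward (adjusted p = 0.00852), but not with an estimated correlation (adjusted p = 0.385) or without verteporfin replicate 1 (adjusted p = 0.111). Of 23 tested 20 had a log2 fold change below 0, with a median of -0.25. EBP, a sterol isomerase gene, was at 40.4 ± 1.32 FPKM in DMSO and 15.9 ± 5.77 FPKM in verteporfin (log2 fold change -1.35), and was the 1 gene that was lower adjusted over the list alone (adjusted p = 0.0419).

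Among immediate early and NF-kB genes JUN and DUSP1 stood out. DUSP1, a phosphatase gene induced by stress kinases, was at 26.8 ± 7.45 FPKM in DMSO and 87.6 ± 43.0 FPKM in verteporfin (log2 fold change 1.55), and it and JUN were the 2 of 20 tested genes that were higher adjusted over the list alone. TNFAIP3, an NF-kB target, had a log2 fold change of 0.73 (adjusted p = 0.593), and 0.29 without verteporfin replicate 1. The list was called by camera (adjusted p = 0.0184) and not with an estimated correlation (adjusted p = 0.473), nor without DMSO replicate 2 (0.0698), verteporfin replicate 1 (0.195) or verteporfin replicate 3 (0.155). The interferon response list (20 tested, 0 past the test, also adjusted over the list alone) lay at the threshold (adjusted p = 0.0496, and 0.473 with an estimated correlation). Its regulators IRF7 and IRF1 had log2 fold changes of 1.06 (adjusted p = 0.438) and 0.67 (adjusted p = 0.537). Of its genes 7 were below 0, among them the interferon-induced ISG15 (-0.42, adjusted p = 0.788), which was at -0.04 without verteporfin replicate 2. The interferon call was lost without DMSO replicate 1 (0.0902), DMSO replicate 2 (0.0847), verteporfin replicate 1 (0.0914) or verteporfin replicate 3 (0.19).

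The B-cell precursor list was not called by camera (adjusted p = 0.663, and 0.896 with an estimated correlation), but was called downward with library weights (0.0463), tried after the data were seen. Of 26 tested 0 passed, over all genes or adjusted over the list alone. Its median was 0.06, while its mean of -0.04 and camera had the other sign. CD22, an inhibitory receptor of B cells, was at 31.2 ± 8.23 FPKM in DMSO and 14.9 ± 1.13 FPKM in verteporfin (log2 fold change -0.99, adjusted p = 0.418). The B-cell maturation list, of which 9 genes were tested, was called upward (adjusted p = 0.0408, and 0.417 with an estimated correlation), with CD69 as the 1 gene that was higher adjusted over the list alone. CD69 marks activation of lymphocytes rather than a stage of maturation. That call was lost without DMSO replicate 1 (0.102), verteporfin replicate 1 (0.105) or verteporfin replicate 2 (0.101). Of 25 markers of other cell types 4 were tested and 0 passed; LYZ was at 2.25 ± 0.281 and 1.73 ± 0.367 FPKM, and S100A9 was above 1 FPKM only in DMSO replicate 2, at 14.7 FPKM.

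The lists of ER chaperones, NRF2 targets, heat shock, autophagy and lysosome, and heme and porphyrin genes were not called. For ER chaperones (19 tested) camera gave an adjusted p of 0.429, with a median of -0.19 and a mean of 0.01; HERPUD1 had a log2 fold change of 1.35 (adjusted p = 0.488, and 0.79 as log2 fold change without verteporfin replicate 2) and the disulfide isomerase gene PDIA3 one of -0.61 (adjusted p = 0.534). For targets of NRF2 (16 tested) the adjusted p was 0.427, and the ferritin heavy chain gene FTH1 had a log2 fold change of 1.23 (adjusted p = 0.422). For heat shock genes (14 tested) it was 0.626, with HSPA1B at 1.21 (adjusted p = 0.418), a gene whose reads are hard to tell from those of its near-identical copy, and AHSA1 at -0.84 (adjusted p = 0.453). Autophagy and lysosome genes (23 tested) had an adjusted p of 0.0667 and a median of 0.19. The cargo receptor gene SQSTM1 had a log2 fold change of 1.37 (adjusted p = 0.491), which was 0.64 without verteporfin replicate 3, and WIPI1 one of 1.18 (adjusted p = 0.402). For heme and porphyrin metabolism (17 tested) the adjusted p was 0.202; ALAS1, the first enzyme of heme synthesis, had a log2 fold change of 0.52 (adjusted p = 0.603) and CPOX one of -1.28 (adjusted p = 0.425). HMOX1 had no matched transcript among the FPKM values and could not be tested. In these lists 0 genes passed over all genes or adjusted over the list alone, and 0 lists were called with an estimated correlation. The Autophagy and lysosome list was called without verteporfin replicate 2 (adjusted p = 0.0367), after quantile normalization (0.038), without both libraries numbered 2 (0.0343) and with library weights (0.0463), the latter pair tried after the data were seen.

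Lists of energy metabolism and of the cell cycle were not called over the 6 libraries, and in them too 0 genes passed over all genes or adjusted over the list alone. Glycolysis and hypoxia genes (27 tested) had an adjusted p of 0.168; PKM, the pyruvate kinase gene, had a log2 fold change of -1.27 (adjusted p = 0.384, and 0.0344 with the replicate block) and the hypoxia-induced ADM one of 2.38 (adjusted p = 0.404). The nuclear respiratory chain list (27 tested) had an adjusted p of 0.202, with NDUFV1 at -0.50, and the mitochondrial one (13 tested) an adjusted p of 0.663, with a median of -0.04 and a mean of 0.07. For G1/S and replication genes (30 tested) the adjusted p was 0.279, with MCM4 at -0.50 (adjusted p = 0.637), and for G2/M genes (28 tested) it was 0.663, with PLK1 at -0.70 (adjusted p = 0.576) and MKI67 at -0.41 (adjusted p = 0.739), which was -0.22 without DMSO replicate 2 and -0.62 without verteporfin replicate 3. Verteporfin replicate 2 decided some of these: without it camera called the Glycolysis and hypoxia list upward (adjusted p = 0.000515) and the nuclear respiratory (0.00298), mitochondrial respiratory (0.000268) and G1/S lists (0.00503) downward. Without verteporfin replicate 3 the Glycolysis and hypoxia list was also called upward (0.0143). With an estimated correlation between genes the adjusted p of these 5 lists over the 6 libraries lay between 0.871 and 0.908.

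**Figure D5:**
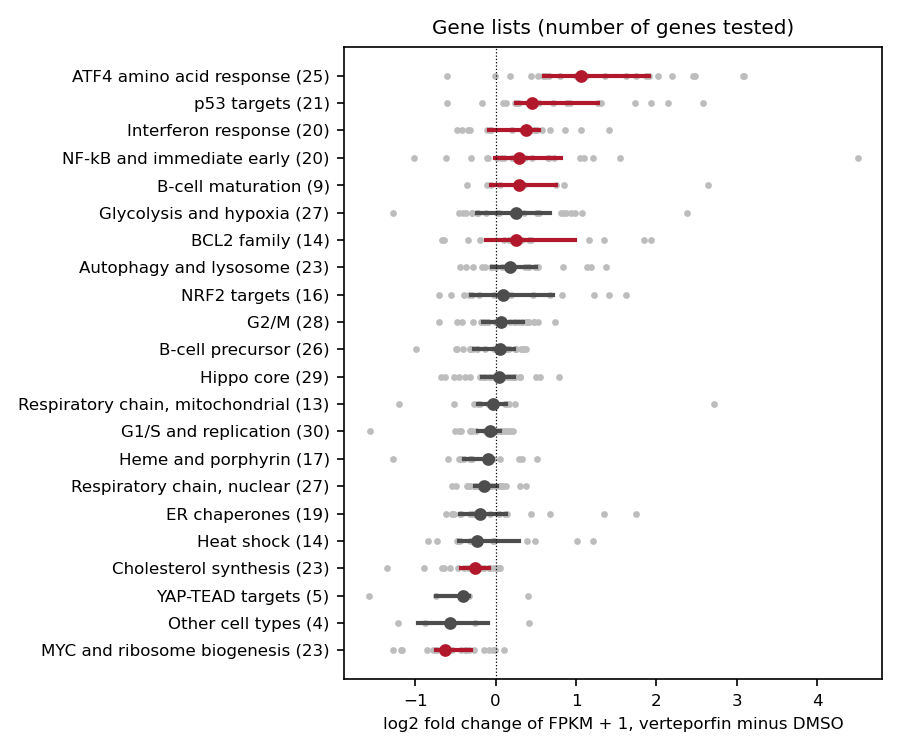
Log2 fold change, verteporfin minus DMSO, of FPKM + 1 for the genes of the 22 lists, with the number of genes tested in brackets. Gray dots are genes, large dots are medians and bars are the quartiles of the genes; red marks the 8 lists with a camera adjusted p under 0.05 at the preset correlation of 0.01, from a median of -0.63 (MYC and ribosome biogenesis) to 1.06 (ATF4 amino acid response), none of which was called with an estimated correlation.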

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

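Of the tests in this part, that of sequencing depth was chosen only after the result was seen.

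Besides FPKM, the deposited values hold a set of whole numbers under repeated transcript identifiers, in which a signal no comparison used was higher with verteporfin. Their sum was 2688 ± 602 per library in DMSO and 6858 ± 2372 in verteporfin (SD, n = 3), a ratio of 2.55, and 2.05 without verteporfin replicate 2. The 2-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 allow, and 0.18 adjusted over 9 measures. Of the entries 1143 ± 184 were above 0 in a DMSO library and 1728 ± 185 in a verteporfin library. The groups did not overlap for 182 entries higher with verteporfin and 3 lower, together 3.88% of the entries. Chance gives 10% of entries without ties, but most of these have ties at 0. Most numbers were small: the median sum over the 6 libraries was 4 and the highest 535, and 2533 entries were above 0 in 1 library only, against 70 in all 6.

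What the whole numbers count is not stated. Reads across ordinary, linear exon junctions are argued against: they should rise with the FPKM of the host gene, while Spearman's rho across 2592 host genes, which are not independent replicates, was 0.186. Only 5 of the 100 protein-coding genes of highest FPKM were among the hosts. These 100 were not limited to genes with several exons, so this count does not bear on the question. Reads across back-spliced junctions, which join an exon to an earlier one in circular RNA, are a candidate explanation. Of the entries 0% lay on single-exon transcripts and 0% on transcripts with 2 exons, against 1.24% and 6.08% of the protein-coding FPKM transcripts. That 0 lay on the mitochondrial chromosome follows from this if its transcripts have 1 exon, and adds no support. Other counts that need several exons would give the same shares.

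The higher sum with verteporfin may come from deeper sequencing of those libraries. The number of FPKM transcripts at 0 was at most 7064 in a verteporfin library and at least 8697 in a DMSO library, as deeper sequencing would give. FPKM do not keep the depth, so deeper sequencing and more such RNA with verteporfin cannot be told apart, and a biological explanation was not tested.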

How the results depend on the processing

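The tests chosen only after the result was seen are those without both libraries numbered 2, with values rescaled without the 3 most abundant transcripts, with library weights and on single transcripts. Unless the setting itself shows it, as with fewer libraries or genes, the cause was not tested.

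The count of 2 genes past the threshold, both changed at least 2-fold, held with no minimum, at a minimum mean of 5 FPKM and after quantile normalization. It was 0 with a pseudocount of 0.1 or 0.01, equal medians, limma without trend, without both libraries numbered 2 and with rescaled values (1126, 1083, 1172, 1140, 1434 and 1129 genes at an unadjusted p under 0.05). It was 0 to 12 leaving out 1 library, 84 with the replicate block (44 higher and 40 lower), all at least 2-fold, 1081 with library weights (693 higher and 388 lower, 811 at least 2-fold; weights 0.363 to 3.88), and 16 genes, 0 of them shared, from 17 of 55388 single transcripts. DDIT3 and DDIT4 kept their direction; their adjusted p lay between 0.00036 and 0.268. The labels do not say whether libraries of the same number share more than the number. Same-number libraries correlated, each minus its group mean, at 0.389, 0.509 and 0.0985, 2 of 3 over 0.1. Of the 6 libraries 5 correlated best with the one of their number, while verteporfin replicate 3 did so with DMSO replicate 1 (0.138). Subtracting the group means makes these correlations depend on each other, so they do not settle whether the numbers pair the libraries.

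All 8 called lists were lost with an estimated correlation and with fry. The adjusted p values were 0.373 and 0.134 for ATF4, 0.385 and 0.233 for p53 and for cholesterol, 0.473 and 0.346 for MYC and interferon, 0.473 and 0.459 for NF-kB, 0.473 and 0.339 for BCL2, and 0.417 and 0.339 for B-cell maturation. Interferon and BCL2 were also lost with no minimum (0.113 and 0.0718), a minimum of 5 FPKM (0.263 and 0.162), a pseudocount of 0.1 (0.0545 each) or 0.01 (0.0575 each), the replicate block (0.0551 each) and rescaled values (0.053 each), interferon after quantile normalization (0.0769) and BCL2 with equal medians (0.0531). B-cell maturation was lost with the replicate block (0.0566) and library weights (0.0941). Leaving out 1 library the adjusted p ran from 1.47e-19 to 1.69e-12 for ATF4, 7.46e-09 to 7.49e-05 for p53, 4.37e-11 to 0.0521 for MYC, 0.00366 to 0.111 for cholesterol, 5.1e-06 to 0.195 for NF-kB, 0.000901 to 0.281 for BCL2, 0.021 to 0.105 for B-cell maturation and 0.017 to 0.19 for interferon. The YAP-TEAD list was not called and kept its direction in each alternative run (0.0521 to 0.473).

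The Hippo core list was called under none of its 19 alternatives; its direction turned at a minimum of 5 FPKM (0.81), after quantile normalization (0.787), with the replicate block (0.945), without both libraries numbered 2 (0.835), with library weights (0.946) and without DMSO replicate 3 or verteporfin replicate 2 (0.743 to 0.922 leaving out any 1 library). In lists not called over the 6 libraries the direction also turned: B-cell precursor at a minimum of 5 FPKM (0.964), after quantile normalization (0.777) and without DMSO replicate 2 (0.996) or verteporfin replicate 3 (0.278); ER chaperones after quantile normalization (0.953) and without verteporfin replicate 1 (0.571; any 1 library 0.186 to 0.705); G2/M with library weights (0.573) and without DMSO replicate 1, verteporfin replicate 1 or 2 (0.92 to 0.922; any 1 library 0.155 to 0.922); other cell types without both libraries numbered 2 (0.902) and DMSO replicate 2 alone (0.979; any 1 library 0.102 to 0.979). Leaving out 1 library turned 4 more, none of them past the threshold where it turned: mitochondrial respiratory chain at 0.26 to 0.638 (any 1 library 0.000268 to 0.638), heat shock at 0.712 (0.256 to 0.833), glycolysis at 0.182 (0.000515 to 0.336) and G1/S at 0.967 (0.00503 to 0.967).

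Some lists were called only under an alternative, each in the direction it had over the 6 libraries. Without verteporfin replicate 2 these were the Autophagy and lysosome list (0.0367), the Glycolysis and hypoxia list (0.000515, and 0.0143 without verteporfin replicate 3), the Respiratory chain, nuclear list (0.00298), the Respiratory chain, mitochondrial list (0.000268) and the G1/S and replication list (0.00503). Without both libraries numbered 2 these were the Autophagy and lysosome list (0.0343), the Glycolysis and hypoxia list (0.00223) and the G1/S and replication list (0.00451). With library weights they were the Autophagy and lysosome list (0.0463), the Respiratory chain, nuclear list (0.0363), the G1/S and replication list (0.00579) and the B-cell precursor list (0.0463). Quantile normalization called the Autophagy and lysosome list (0.038).

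Of 87 named genes 80 kept their direction under each alternative and 7 turned. Their log2 fold changes leaving out 1 library ran from -1.11 to 0.0331 for ARHGEF17, -0.044 to 0.60 for MDM2, -0.47 to 0.0368 for MOB1A, -0.0657 to 4.58 for MT-ND4, -0.0627 to 0.22 for SAV1, -0.015 to 0.63 for STK4 and -1.88 to 0.11 for S100A9 (0.17 without both libraries numbered 2). Named genes newly past the threshold numbered 57 with library weights, 23 with the replicate block, 6 without verteporfin replicate 1 and 7 without verteporfin replicate 2. Depth limits are unknown, because FPKM do not keep it.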

Other observations

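In this part the histone genes, the test of S phase genes and all counts of other splits of the libraries were chosen only after the result was seen.

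Histone genes, which belong to no list, were mostly higher with verteporfin. Of 59 tested 54 had a log2 fold change above 0 and 5 below, with a median of 0.62, which was 0.57 with equal medians and 0.48 after quantile normalization. At an unadjusted p under 0.05 limma gave 23 higher and 0 lower; 1 was higher adjusted over the histone genes alone. H2AC6 was at 9.46 ± 3.19 FPKM in DMSO and 73.9 ± 37.9 FPKM in verteporfin (SD, n = 3), and the linker histone gene H1-3 at 897 ± 279 and 1834 ± 836 FPKM (log2 fold change 0.96, and 0.64 without verteporfin replicate 1). For the group, chosen after its values were seen, camera gave an unadjusted p of 5.35e-15, and of 0.0419 with an estimated correlation of 0.175. The lists above were given with adjusted p values. Unadjusted, camera with an estimated correlation gave p = 0.0169 for the ATF4 list and p = 0.0466 for the p53 list. Histone genes took 5.59% to 6.74% of the summed FPKM in DMSO libraries and 7.87% to 10.3% in verteporfin libraries (2-sided exact permutation p = 0.1, the smallest possible, and 0.18 adjusted over 9 measures). Reads shared between histone paralogs can move single genes, and also the share of the family where paralogs differ in length, which was not tested.

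A general favouring of short protein-coding transcripts is argued against as the cause. The 3461 other protein-coding genes of up to 1666 nt, the 90th percentile of histone gene length, had a median log2 fold change of -0.06 (-0.0602, quartiles -0.35 to 0.26). Of 10000 random lists of them, which treat genes as independent, 0 had a median as high as the histone genes. The genes were not matched to histone genes in length below that limit, and noncoding RNA was left out. Favouring of the shortest RNA therefore stays open. RMRP, a noncoding RNA of 268 nt, had 8223 to 9536 FPKM in DMSO and 13131 to 18082 FPKM in verteporfin. AL139099.4, of 300 nt, overlapped between the groups (30373 to 49852 and 25676 to 56576 FPKM). More cells in S phase, when most histone genes are transcribed, should raise genes of G1/S and replication as well. That list had a median of -0.07 (-0.0723, quartiles -0.22 to 0.06), and its upper quartile lay below the histone median of 0.62. Of its 30 genes 10 had a log2 fold change above 0 and 20 one below 0. For the genes of that list these values argue against S phase as the main cause, while a smaller contribution stays open. A different capture of histone RNA, which largely lacks a poly(A) tail, was not tested.

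The share of summed FPKM in transcripts annotated as retained introns was 11.7% ± 0.318 in DMSO and 10.1% ± 0.342 in verteporfin (SD, n = 3; 2-sided exact permutation p = 0.1, adjusted p = 0.18). Mitochondrial transcripts took 4.04% and 5.33% of the FPKM in the libraries numbered 2, the highest share in each group. MT-ND4 was at 1.17 FPKM in DMSO replicate 3 and between 335 and 1899 FPKM in the other libraries.

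The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2 genes past the threshold, both at least 2-fold, and the highest other split 1; 1 split of 10 gave as many. It called 8 lists and the highest other split 8, with as many in 3 splits. The split of DMSO replicates 1 and 3 and verteporfin replicate 1 against the others gave 2666 genes at an unadjusted p under 0.05. That of DMSO replicate 1 and verteporfin replicates 1 and 3 gave 1164. Both counts are above the 1145 of the real split, which points to a structure of the samples that the treatment does not follow.

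For single lists the camera p of the real split and the lowest of the other splits were 2.24e-19 and 7.99e-11 for ATF4, 9.14e-08 and 4.88e-05 for p53, 0.00155 and 0.00556 for cholesterol, 0.0111 and 0.0132 for B-cell maturation and 0.0172 and 0.0571 for interferon, so that 1 split of 10 gave a p as small. They were 6.7e-08 and 3.87e-10 for MYC (2 splits), 0.018 and 0.00474 for BCL2 (3 splits), 0.0324 and 0.0107 for YAP-TEAD (3 splits), 0.00418 and 6.69e-06 for NF-kB (4 splits) and 0.906 and 0.318 for Hippo core (9 splits).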
